A study of Homo sapiens with 12 samples.

How the data were processed

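RNA was measured in 12 libraries of LNCaP cells with an inducible hairpin against PRMT5, 3 in each of 4 groups set by doxycycline and irradiation. Per the labels' protocols, RNA was isolated with Trizol and polyadenylated RNA was used for the libraries. The deposited values are raw counts per gene, in 2 tables of 6 libraries, one per irradiation state; per the file headers they have the layout of featureCounts output, with the merged exon coordinates and length of each gene. The submitters' processing notes name STAR 2.5, featureCounts, Subread 1.5.3, edgeR 3.20.8 and the genome build GRCh38. The aligner's options, the treatment of reads that map to several places, the strand setting, the annotation release and the sequencing runs are not given in the sources used here. Counts of overlapping, antisense or near-identical genes are therefore treated as uncertain. Of the exon positions and of the 50-base words of each named gene, the percent also found in another gene was computed from the coordinates in the tables and from GENCODE 29 transcripts.

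The tables listed 63299 genes, of which 34300 had a count in any library; 57492 identifiers (90.8%) were found in GENCODE 29. No line of either table named anything but a gene, so none was left out of the totals. Every column was matched to its sample by the sample number in the labels. Total counts ran from 14801939 to 33158865 per library, a ratio of 2.24. A count of 3, the upper limit that a count of 0 allows, corresponded to between 0.0905 and 0.203 CPM in a library, which covers counting error only. Replicates of a group were compared by a chi-square of their counts per gene, and none were alike within sampling noise.

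Fold changes were computed from the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17191. Libraries were scaled by TMM, and 1 robust quasi-likelihood model with a mean per group was fitted to all 12, which left 8 residual degrees of freedom and a biological coefficient of variation of 0.216. The 5 comparisons were knockdown against control without and with irradiation, irradiated against non-irradiated in controls and in knockdowns, and the difference of the knockdown effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a single gene is from this test unless another is named. Standard errors are of the log2 fold change, derived as its absolute value divided by the square root of the quasi-likelihood F statistic. PRMT5 was also tested with a 2-sided exact permutation test.

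Fixed gene lists numbered 18, of which 2, with 1 gene fixed in advance, are not reported here; they stay in the adjustment and in the counts of lists called. The other 16 are the methylosome and other arginine methyltransferases (13 members), homologous recombination (28), non-homologous end joining (19), Fanconi anemia (18), p53 targets (34), DNA replication and G1/S (39), G2/M and mitosis (35), Sm proteins and snRNP assembly (24), interferon response (30), integrated stress response and ATF4 targets (25), mitochondrially encoded messenger RNAs (13), cholesterol synthesis and uptake (23), and markers of neuroendocrine (15), fibroblast (12), leukocyte (12) and basal epithelial cells (8). They were tested with camera in limma 3.58.1, through edgeR's method for counts, with a preset correlation of 0.01. List means per library and per pair are of log2 CPM with a prior count of 2. Their p-values were adjusted over the 18 lists of a comparison. The adjusted p of a list is from camera. No list call held with an estimated correlation in any comparison. With fry, which asks whether a list moves on balance one way, only the mitochondrial list passed without the block, in the irradiation comparisons (adjusted p = 0.00394 in controls and 0.0237 in knockdowns). Fry with a replicate block was chosen after the data were seen. With the block within tables it passed these reported lists for the knockdown without irradiation: methylosome, interferon and mitochondrial (each 0.0191). For the knockdown with irradiation it passed methylosome (0.0283) and interferon (0.0293). The methylosome list holds PRMT5 and was not tested without it. For irradiation the block ran across tables, where samples share only a number and no pairing was seen. There fry passed mitochondrial (0.0141 in controls and 0.0316 in knockdowns) and neuroendocrine (0.0166 and 0.0285). The median, mean and count of signs of a list are over its tested members.

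Groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were PRMT5 and per knockdown comparison the 10 largest positive and 10 largest negative fold changes among called genes with a symbol, a mean of at least 5 CPM and no overlap between the libraries of both groups. Per irradiation comparison the limit was 6 each way, and up to 4 members of each list with the smallest p in a comparison were added. ABHD2 and TNFAIP1, and the genes named only in the closing section, were chosen after their values were seen, and so was the word TTCCCTA.

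Replicate numbers, which come from the sample titles, were checked as pairs within each table. Deviations from the group means correlated at 0.233 to 0.775 between the knockdown and control library of the same number in all 6 pairs, and at -0.677 to 0.476 between other numbers. The numbers were therefore taken as pairs within a table, and the fit with 6 replicate blocks left 4 residual degrees of freedom and a coefficient of variation of 0.0978.

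Alternatives were scaling by RLE or by library size only, DESeq2 1.42.0 and limma-voom in place of edgeR, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries and a mean of 10 CPM), a fold of at least 2, the replicate block within or across tables, each library left out in turn, fits of only the 6 libraries compared, and for lists an estimated correlation and fry. Chosen after seeing the data were leaving out either pair numbered 1, alone or with the block, DESeq2 with the block, a fit of only genes with little shared sequence or position, fry with the block, and the overlap of knockdown calls with the block.

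The fit was tested on simulated counts of 17191 genes with 200 changed. Of genes changed 1.5-, 2- and 4-fold it called 11.9, 50.7 and 92.4% for the knockdown without irradiation, 5.97, 58.2 and 90.9% for the knockdown with irradiation, 11.9, 47.8 and 84.8% for irradiation in controls, 5.97, 65.7 and 90.9% for irradiation in knockdowns and 1.49, 13.4 and 72.7% for the difference. The false share of calls was 2.83, 3.74, 4.00, 6.09 and 3.33% in that order. These counts were drawn around 1 mean per gene with no pair effect. The real libraries correlate as pairs, so these shares may not hold for the real fit without the block. With the replicate block 62.7, 82.1 and 98.5% were called for the knockdown without irradiation, 64.2, 98.5 and 98.5% with irradiation, and 46.3, 71.6 and 93.9% for the difference. The false shares with the block were 12.0, 10.8 and 10.8%, above the intended 5%, so blocked calls are less firm than their adjusted p says.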

Results

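Messenger RNA was sequenced from LNCaP cells, a prostate cancer line grown from a lymph node metastasis. The cells carried a doxycycline-inducible short hairpin RNA against PRMT5, the main enzyme that places symmetric dimethyl marks on arginines of histones and of spliceosomal Sm proteins. Knockdown cultures received doxycycline at 1 µg/mL every 48 h and control cultures received none. Irradiated cultures received 2 Gy and were harvested 24 h later. The 12 libraries formed 4 groups of 3: non-irradiated control, non-irradiated knockdown, irradiated control and irradiated knockdown. The design asks what loss of PRMT5 and irradiation, alone and together, do to the transcriptome.

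Total gene counts per library ran from 14801939 to 33158865. The group means, in mega-counts (M), were 19.1 ± 4.03 M for non-irradiated controls, 24.1 ± 5.89 for non-irradiated knockdowns, 29.7 ± 3.20 for irradiated controls and 27.1 ± 3.54 for irradiated knockdowns (SD, n = 3 each). Hairpin induction and doxycycline always came together, so a knockdown comparison holds the effect of both. The non-irradiated and the irradiated libraries came from 2 separate deposited count tables. Irradiation therefore cannot be told apart from any other difference between those tables. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 libraries of a group were alike within sampling noise: chi-square per gene was 9.795 for the closest (irradiated knockdown replicates 2 and 3) and 144 for the farthest (irradiated control replicates 1 and 2).

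PRMT5 (ENSG00000100462.15) lies on chromosome 14 at 22920511 to 22929585 (GRCh38). Its TMM-normalised level in the non-irradiated controls was 186, 190 and 198 CPM (counts scaled to a common library size, per mega-count), and in the non-irradiated knockdowns 26.6, 30.8 and 32.8 CPM. The irradiated controls held 230, 187 and 187 CPM and the irradiated knockdowns 31.3, 26.9 and 24.9 CPM. The knockdown libraries thus kept 15.7% of the control mean without irradiation and 13.8% with it, and no library went against its label. The log2 fold change was -2.67 (SE 0.13, adjusted p = 2.49e-06) without and -2.86 (SE 0.13, adjusted p = 1.20e-06) with irradiation in edgeR's quasi-likelihood test. A 2-sided exact permutation test of 3 against 3 libraries gave p = 0.1 in both, the smallest it can give. Of the exon positions of PRMT5, 27.1% are also covered by another gene, so part of its counts is uncertain.

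Between irradiated and non-irradiated libraries PRMT5 differed by 0.07 in controls (adjusted p = 0.750) and -0.12 in knockdowns (adjusted p = 0.626). The control value was -0.09 when scaled by library size only.

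**Figure D1:**
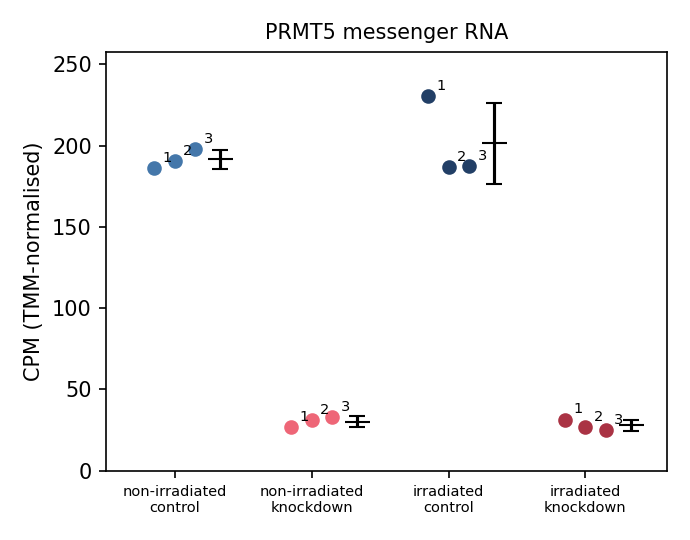
PRMT5 messenger RNA in each of the 12 libraries, in TMM-normalised CPM on an axis from 0; points are libraries marked by replicate number, bars the mean ± SD of 3. PRMT5 lies between 24.9 and 32.8 CPM in the 6 knockdown libraries and between 186 and 230 CPM in the 6 controls.

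Knockdown without irradiation lowered 207 genes. Those named here were taken by the rule for named genes, and no enrichment of roles was tested among them. RNF14, a ubiquitin ligase gene (chromosome 5, 141958328 to 141990291), fell from 101 ± 2.26 to 33.0 ± 3.22 CPM (log2 fold change -1.62, SE 0.15, edgeR adjusted p = 0.000958). SLITRK5, a neuronal transmembrane protein gene (chromosome 13, 87672615 to 87696272), fell from 30.7 ± 0.883 to 2.32 ± 0.925 CPM (-3.69, SE 0.59, adjusted p = 0.0118). The vesicular polyamine transporter SLC18B1 fell from 91.3 ± 1.06 to 30.4 ± 6.10 CPM, PTER from 43.9 ± 1.91 to 12.1 ± 1.89 CPM and the glycerophosphodiesterase gene GDPD1 from 34.3 ± 1.54 to 10.6 ± 1.95 CPM. Their log2 fold changes were -1.59, -1.87 and -1.69 (adjusted p = 0.00203, 0.00199 and 0.00203). CNGB3, a channel subunit of cone photoreceptors, fell by 2.32 on the log2 scale from 9.97 ± 1.34 CPM. The serine protease gene TMPRSS11E fell by 2.34 (adjusted p = 0.00718) and FAM234B by 1.61 (adjusted p = 0.0445). MAATS1 fell by 1.80, but 52.0% of its 50-base words also occur in another gene, so its count is uncertain.

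Fewer genes rose. NPPC, which encodes C-type natriuretic peptide, rose from 3.20 ± 1.63 to 21.3 ± 5.01 CPM (log2 fold change 2.72, SE 0.53, edgeR adjusted p = 0.0324), and the synaptotagmin gene SYT4 from 16.1 ± 5.86 to 83.1 ± 35.0 CPM (2.37, SE 0.37, adjusted p = 0.0113). LDOC1 rose from 37.9 ± 2.60 to 97.9 ± 5.98 CPM (1.37, adjusted p = 0.00441). OTUD3, a deubiquitinase gene, rose from 20.2 ± 4.05 to 47.1 ± 7.88 CPM. TDP1, which frees DNA ends from stalled topoisomerase I, rose from 51.4 ± 8.85 to 118 ± 31.9 CPM (1.20, adjusted p = 0.0202). CDR2L rose by 1.19, the AMPK-related kinase NUAK2 by 1.00, LRP5L by 0.99, NWD1 by 0.97 and the long non-coding RNA RP11-693J15.6 by 2.95.

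In all, 265 of 17191 tested genes passed an adjusted p of 0.05 without irradiation, 58 higher and 207 lower with knockdown, and 239 were protein-coding. In each of the 265 the 3 libraries of one group lay above all 3 of the other. Of all tested genes 31.1% were so separated, against 10% by chance. With replicate number within the table as a block, 4776 genes were called, 2349 higher and 2427 lower, and all 265 were called the same way. On simulated counts 12.0% of the calls of that blocked fit were false, above the intended 5%, so the larger count is less firm. The count was 119, 63 and 48 without control replicates 1, 2 and 3, and 31 and 35 without knockdown replicates 2 and 3. Of the 22 named genes called here, leaving out any 1 library kept RNF14, SLC18B1, GDPD1, PTER, CNGB3, LDOC1 and PRMT5. As few as 8 of the 22 stayed called without knockdown replicate 3, 9 without knockdown replicate 2 or control replicate 3, 12 without control replicate 2 and 13 without control replicate 1.

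Among the fixed gene lists, proliferation genes ranked higher and ATF4 target genes lower in the non-irradiated knockdown. All 39 genes of the DNA replication and G1/S list had a positive log2 fold change (median 0.86), as had all 35 of the G2/M and mitosis list (median 0.89). No member of either list passed the test by itself, over all genes or adjusted over the list alone. Values were 1.45 for the helicase subunit MCM2 and 0.67 for the ribonucleotide reductase subunit RRM1 (edgeR adjusted p = 0.166 and 0.147). With the replicate block 17 replication genes were called higher, MCM2 (adjusted p = 0.0367) and RRM1 (adjusted p = 0.0184) among them, and no G2/M gene. The camera test with its preset correlation of 0.01 gave an adjusted p of 9.32e-11 for replication and 1.62e-10 for G2/M. For both lists the adjusted p = 0.571 with an estimated correlation. The rise was not shared by every pair: the mean G2/M change, knockdown minus control, was -0.93 in pair 1 and 2.56 and 1.90 in pairs 2 and 3, and the replication change 0.11, 1.62 and 1.36. Leaving out 1 library in turn moved the G2/M median from 0.46 to 1.98, and it stayed called.

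DNA repair lists moved in part. Of 28 homologous recombination genes 22 were positive (median 0.55, camera adjusted p = 0.00251; adjusted p = 0.571 with an estimated correlation). None passed over all genes or adjusted over the list alone, and with the block 3 were higher and 1 lower. Of 18 Fanconi anemia genes 13 were positive (median 0.34, camera adjusted p = 0.0141; adjusted p = 0.571 with an estimated correlation). SLX4, a scaffold of structure-specific nucleases, rose from 23.8 ± 1.97 to 36.3 ± 4.25 CPM (log2 fold change 0.61, SE 0.13, edgeR adjusted p = 0.0415). SLX4 was the only member called, also adjusted over the list alone, and its call ended when scaled by library size only or with no filter on low counts. With the block 4 Fanconi genes were higher and 2 lower. By pair the mean change was -0.24, 1.18 and 0.99 for recombination and -0.05, 0.53 and 0.54 for Fanconi anemia, so pair 1 did not share the rise. The Fanconi list call ended without knockdown replicate 2 (adjusted p = 0.0613) and without control replicate 3 (adjusted p = 0.0647), in a range of 1.46e-07 to 0.571 over its alternatives. The 18 non-homologous end joining genes gave a median of -0.02, with a test in the positive direction (camera adjusted p = 0.719).

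Targets of ATF4, the transcription factor of the integrated stress response, ranked lower: 23 of 25 were negative (median -0.53, camera adjusted p = 1.52e-06; adjusted p = 0.571 with an estimated correlation). ATF3, itself a stress-induced transcription factor, fell from 104 ± 15.8 to 40.4 ± 6.67 CPM (log2 fold change -1.37, SE 0.23, edgeR adjusted p = 0.0142). It was the only member called over all genes, 4 were lower adjusted over the list alone, and 2 with the block. The 13 mitochondrially encoded messenger RNAs ranked higher (12 positive, median 0.28, camera adjusted p = 0.000368; adjusted p = 0.571 with an estimated correlation). None passed over all genes or adjusted over the list alone, and with the block 8 were called higher. The share of all counts from mitochondrial genes was 5.49 ± 0.392% in controls and 6.09 ± 0.108% in knockdowns. Of the 24 genes for Sm proteins and their assembly 18 were positive (median 0.21, camera adjusted p = 0.0144; adjusted p = 0.681 with an estimated correlation). No Sm gene was called over all genes or adjusted over the list alone, and 10 were higher with the block.

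The list of the methylosome and other arginine methyltransferases, which holds PRMT5 itself, ranked lower (8 of 12 negative, median -0.09, camera adjusted p = 0.00634; adjusted p = 0.571 with an estimated correlation). PRMT5, the gene knocked down, was its only call over all genes. The list was not tested without PRMT5, so the list call does not speak for the other members. Adjusted over the list alone PRMT3 also passed, at a log2 fold change of -0.38, and with the block 4 were higher and 4 lower. This list call ended without knockdown replicate 1 (adjusted p = 0.0604, in a range of 0.00250 to 0.571 over its alternatives).

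The remaining lists gave no call without irradiation. The p53 target list stood at a median of 0.04 (camera adjusted p = 0.636), with no member called over all genes or adjusted over the list alone and 7 higher and 3 lower with the block. The interferon list stood at -0.14 (adjusted p = 0.283; with the block 5 genes lower and a fry adjusted p of 0.0191). Its mean was lower in the knockdown library of all 6 pairs of both irradiation states, by -0.30 to -0.11. Cholesterol genes stood at 0.16 (20 of 22 positive, adjusted p = 0.0725) and were called with the block (adjusted p = 0.0202; with the block and an estimated correlation adjusted p = 0.668). The cholesterol list also passed without control replicate 1 (adjusted p = 0.00428), knockdown replicate 2 (0.0282) or knockdown replicate 3 (0.000731). Markers of other cell types stayed uncalled: neuroendocrine median 0.03 with a mean of -0.19 (adjusted p = 0.913), fibroblast -0.11 with a mean of 0.19 and a positive test (0.230; 2 higher adjusted over the list alone), basal epithelial 0.03 (0.913) and the single tested leukocyte gene LCP1 0.55 (0.578). Fibroblast markers passed without control replicate 1 (adjusted p = 0.000688). With 1 library left out in turn, the cholesterol median ran from -0.03 to 0.31 and the fibroblast median from -0.61 to 0.72. In these fits the highest camera adjusted p was 0.9996 and 0.852. Of the 12 leukocyte markers 11 were too low to test, among them PTPRC with a mean count of 0.0833.

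After irradiation the knockdown again lowered SLITRK5, CNGB3, PTER and RNF14. RNF14 fell from 95.7 ± 9.29 to 36.9 ± 8.30 CPM (log2 fold change -1.37, SE 0.15, edgeR adjusted p = 0.00419) and SLITRK5 from 21.5 ± 13.1 to 1.53 ± 0.934 CPM (-3.80, SE 0.60, adjusted p = 0.0205). MCCC2, a subunit of the leucine-degrading carboxylase, fell from 408 ± 71.9 to 154 ± 34.8 CPM (-1.40, SE 0.20, adjusted p = 0.0153). PSMB5, a catalytic subunit of the proteasome (chromosome 14, 23016543 to 23035230), fell from 201 ± 55.3 to 76.8 ± 19.2 CPM (-1.39, SE 0.20, adjusted p = 0.0142); it lies 87.0 kb from PRMT5. The alcohol dehydrogenase gene ADH1C fell from 10.9 ± 1.27 to 3.31 ± 0.467 CPM, but 11.7% of its 50-base words occur in another gene. OTUD3 was the only gene called higher, from 18.6 ± 1.22 to 36.0 ± 5.04 CPM (0.95, SE 0.17, adjusted p = 0.0461). Its call ended when scaled by library size only and in limma-voom.

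Of 17191 genes 51 were called with irradiation, 1 higher and 50 lower, and 48 were protein-coding. All 51 had fully separated libraries, a state that 13.5% of all tested genes reached against 10% by chance. With the block 1974 genes were called, 934 higher and 1040 lower, all 51 among them in the same direction. On simulated counts 10.8% of the calls of that blocked fit were false. Without control replicate 1 the count was 254, without control replicates 2 and 3 it was 18 and 19, and without knockdown replicates 2 and 3 it was 7 and 4. RNF14 and PRMT5 stayed called whichever library was left out. Of the 11 named genes called, 2 stayed without knockdown replicate 3, 3 without knockdown replicate 2, 7 without control replicate 2, 8 without control replicate 3 and 9 without knockdown replicate 1. In the fit of only the 6 irradiated libraries PRMT5 alone of the 11 stayed called. RNF14 and the others therefore depend on the filter, scaling and spread shared with the non-irradiated libraries.

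Of the 50 genes lower in the irradiated knockdown, 48 were also among the 207 lower without irradiation, against 0.602 for independent lists. The 2 comparisons have no library in common, but both take the spread of each gene from 1 fit. OTUD3 was called higher in both, against 0.00337. In fits of only the 6 libraries compared, which called 1 gene with irradiation, the overlap was 1. In the fit of all 12 libraries, all 265 genes called without irradiation had the same sign with it. With the block 677 genes were higher and 801 lower in both (128 and 147 for independent lists), and 5 and 1 of the genes higher and lower without irradiation were called in the opposite direction with it. Across genes, which are not independent replicates, the 2 sets of fold changes had a Pearson correlation of 0.55 and a Spearman correlation of 0.55. Among the shared genes, the lipase gene ABHD2 stood at -1.20 and -1.21, TNFAIP1 at -1.20 and -1.21, and PSMB5 at -1.27 and -1.39. Of the 44 shared lower genes other than PRMT5 with an annotated 3′ untranslated region, 20 hold the word TTCCCTA in it, ABHD2, RNF14, MCCC2 and GDPD1 among them, against 6.32 in length-matched gene sets.

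**Figure D2:**
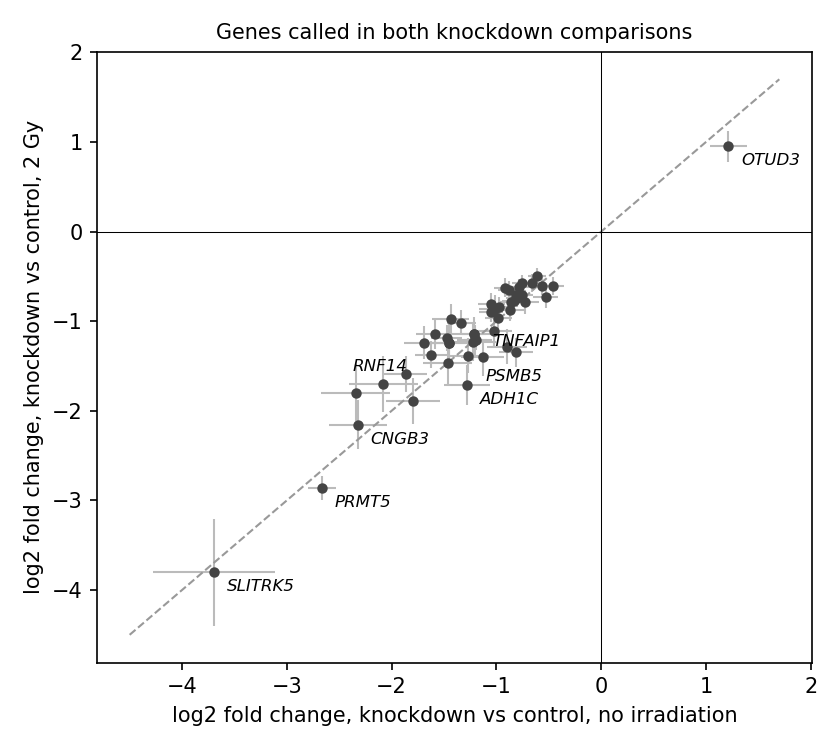
Each point is 1 of the 49 genes called in both knockdown comparisons, placed by its log2 fold change without (x) and with (y) 2 Gy; bars are ± SE and the dashed line marks equal change. Of these genes 48 lie in the lower left, PRMT5 at -2.67 and -2.86, and OTUD3 alone in the upper right.

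Proliferation genes lay the other way in the irradiated knockdown. All 35 G2/M genes were negative (median -1.08, camera adjusted p = 3.78e-14; adjusted p = 0.633 with an estimated correlation) and 38 of 39 replication genes were (median -0.46, camera adjusted p = 0.0125; adjusted p = 0.772 with an estimated correlation). No member of either list was called over all genes or adjusted over the list alone, and with the block 2 replication genes were lower. Without irradiated control replicate 1, a library that stood apart from the others, the replication list turned to 0.44 (adjusted p = 0.0116), but without the whole pair 1 it stood at -0.11 and was not called (adjusted p = 0.390; left out after the data were seen). Its call ended at -0.26 without knockdown replicate 2 (adjusted p = 0.450) and at -0.28 without knockdown replicate 3 (adjusted p = 0.415), in a range of 3.67e-08 to 0.772 over its alternatives. ATF4 targets were again negative, 25 of 25 (median -0.70, camera adjusted p = 3.78e-12; adjusted p = 0.633 with an estimated correlation). By pair the mean change of this list was 0.27 in pair 1, the other way, and -1.01 and -1.07 in pairs 2 and 3. None was called over all genes, 16 were lower adjusted over the list alone and 1 with the block; ATF3 stood at -0.67 (edgeR adjusted p = 0.357).

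Targets of p53, the transcription factor activated by DNA damage, ranked higher in the irradiated knockdown: 25 of 33 were positive (median 0.17, camera adjusted p = 0.000438; adjusted p = 0.650 with an estimated correlation). None was called over all genes or adjusted over the list alone; with the block 8 were higher, such as BTG2 at 0.47 (edgeR adjusted p = 0.375, with the block 0.0105). The p53 call ended without irradiated control replicate 1 (0.12, adjusted p = 0.205, in a range of 7.92e-06 to 0.650 over its alternatives). Mitochondrial messenger RNAs ranked higher (10 of 13 positive, median 0.17, camera adjusted p = 0.0125; adjusted p = 0.633 with an estimated correlation). None was called over all genes or adjusted over the list alone, and 2 were with the block. That list call ended without knockdown replicate 1 (adjusted p = 0.124) and control replicate 2 (adjusted p = 0.209), in a range of 0.000728 to 0.633. The share of all counts from mitochondrial genes was 6.95 ± 0.350% in irradiated controls and 7.02 ± 0.443% in irradiated knockdowns, close to equal. The methylosome list ranked lower (7 of 12 negative, median -0.07, camera adjusted p = 5.20e-05, or 0.633 with an estimated correlation). PRMT5, the gene knocked down, was its only call over all genes and adjusted over the list alone. With the block 1 was higher and 3 lower. The list was not tested without PRMT5, so its call does not speak for the other members.

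Other lists were not called in the irradiated knockdown. Homologous recombination genes stood at -0.24 (camera adjusted p = 0.108) and passed without knockdown replicate 1 (0.00388) or control replicate 3 (0.00476). Fanconi anemia genes stood at -0.27 (adjusted p = 0.137) and passed without knockdown replicate 1 (0.0203), control replicate 2 (0.0212) or control replicate 3 (0.0226). Sm genes stood at 0.09 (adjusted p = 0.110) and passed without control replicate 1 (0.000130) or knockdown replicate 3 (0.00940). Cholesterol genes stood at 0.10 (adjusted p = 0.224) and passed without control replicate 1 (0.0427). With 1 library left out in turn, the recombination median ran from -0.55 to 0.02 and the Fanconi median from -0.43 to 0.02. The Sm median ran from -0.06 to 0.30 and the cholesterol median from -0.04 to 0.21. In these fits the highest camera adjusted p was 0.938, 0.938, 0.984 and 0.809 in that order. The other medians were 0.02 with a mean of -0.03 and a positive test for end joining (adjusted p = 0.765), -0.14 for interferon (0.127; fry with the block 0.0293), -0.01 for neuroendocrine (0.994), -0.23 with a mean of 0.08 and a positive test for fibroblast markers (0.392; 1 higher adjusted over the list alone), -0.38 for basal epithelial markers (0.765) and 0.08 for LCP1 (0.785).

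Whether the knockdown effect itself differed between the irradiation states was tested as an interaction. No gene passed in edgeR, without or with the block, where 350 and 2093 genes had an unadjusted p under 0.05. About 860 would by chance. The count without the block lies below that and the count with it above, so the lack of calls without the block says little. DESeq2 and limma-voom also called none, with 410 and 373 genes at an unadjusted p under 0.05. DESeq2 with the block called 61, 15 higher and 46 lower. The smallest adjusted p in the blocked edgeR fit was 0.173. Without the non-irradiated pair 1, chosen after the data were seen, edgeR called 47 genes, or 712 with the block. The difference was -0.19 (SE 0.18) for PRMT5.

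Of the gene lists 5 differed in this test under the preset correlation, those of proliferation, repair and p53 genes. The median difference, irradiated minus non-irradiated, was -1.95 for G2/M (35 of 35 negative, camera adjusted p = 1.95e-68) and -1.25 for replication (39 of 39, adjusted p = 1.18e-34). It was -0.53 for homologous recombination (23 of 28, adjusted p = 7.41e-11), -0.53 for Fanconi anemia (14 of 18, adjusted p = 9.53e-08) and 0.14 for p53 targets (28 of 33 positive, adjusted p = 0.00458). With an estimated correlation none was called (adjusted p = 0.103, 0.184, 0.170, 0.170 and 0.777). Leaving out 1 library in turn moved the median from -3.06 to -1.51 for G2/M, -1.71 to -0.49 for replication, -0.80 to -0.31 for recombination and -0.70 to -0.28 for Fanconi anemia, and these 4 stayed called. Adjusted over the list alone 26 G2/M genes differed and, with the block, 24 replication genes. An exact permutation test of the G2/M change in 3 pairs against 3 gave p = 0.2, and of the replication and the Fanconi change p = 0.1, the smallest possible (each 0.6 adjusted over the 18 lists). The p53 difference lost its call without non-irradiated knockdown replicate 2 (adjusted p = 0.0572) or 3 (0.0709), non-irradiated control replicate 3 (0.191), irradiated control replicate 1 (0.387) or irradiated knockdown replicate 2 (0.123), in a range of 1.79e-08 to 0.975. Its call held without the other libraries.

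The other 13 lists were not called in the difference. With the block Sm genes (median -0.12, adjusted p = 0.256) and mitochondrial messenger RNAs (-0.12, 0.0697) were called at adjusted p = 0.0294 and 0.0298. Both were lost with the block and an estimated correlation, at adjusted p = 0.777 and 0.736. ATF4 targets stood at -0.23 (adjusted p = 0.689), but at -0.53 without irradiated control replicate 1 (2.21e-19) and at -0.35 without non-irradiated knockdown replicate 2 (0.0259). Sm genes also passed without irradiated knockdown replicate 1 (0.0102), irradiated control replicate 2 (0.0389) or 3 (0.00447). Mitochondrial messenger RNAs passed without non-irradiated control replicate 2 (0.00415), non-irradiated knockdown replicate 3 (0.0107), irradiated knockdown replicate 1 (0.0398) or irradiated control replicate 2 (0.0129). Cholesterol genes passed without non-irradiated control replicate 1 (0.0368) or knockdown replicate 3 (0.00403), and fibroblast markers without non-irradiated control replicate 1 (0.00110). With 1 library left out in turn, medians ran from -0.53 to -0.02 for ATF4 targets and -0.20 to 0.08 for Sm genes. They ran from -0.23 to -0.05 for mitochondrial messenger RNAs, -0.20 to 0.06 for cholesterol and -0.76 to 0.36 for fibroblast markers. The highest camera adjusted p was 0.986, 0.8365, 0.510, 0.9535 and 0.997 in that order. With all libraries adjusted p was 0.429 for cholesterol, 0.685 for fibroblast and 0.689 for methylosome, leukocyte and basal epithelial lists. It was 0.911 for end joining and neuroendocrine lists and 0.944 for interferon.

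**Figure D3:**
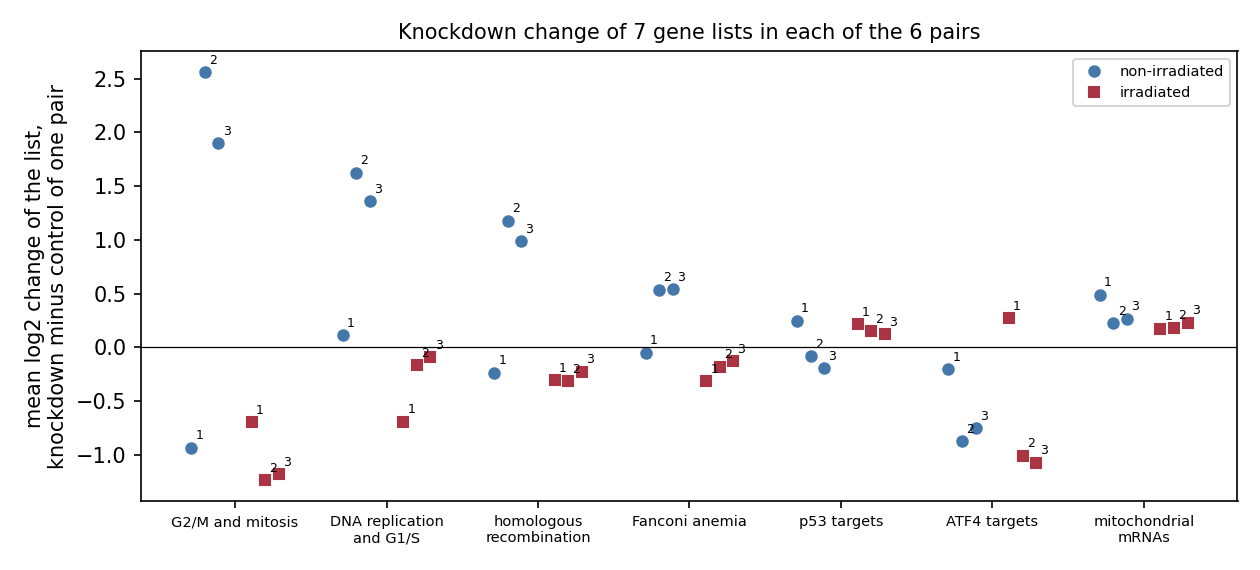
Mean log2 change of 7 gene lists, knockdown minus control, in each of 3 non-irradiated (blue circles) and 3 irradiated pairs (red squares); the number beside a point is the pair. G2/M genes lie at -0.93, 2.56 and 1.90 in the non-irradiated and at -0.69, -1.24 and -1.18 in the irradiated pairs.

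Irradiated and non-irradiated controls, compared to ask how the cells had changed 24 h after 2 Gy, differed in single genes, among them 4 of 33 p53 targets and 3 of 25 ATF4 targets; the list calls given below were all lost with an estimated correlation. The p53 targets were higher: BTG2, an antiproliferative gene, at 143 ± 7.93 against 71.3 ± 9.99 CPM (log2 fold change 1.01, SE 0.17, edgeR adjusted p = 0.0149), and SESN1, a stress-induced inhibitor of mTORC1, at 225 ± 26.8 against 123 ± 11.3 CPM (0.87, SE 0.14, adjusted p = 0.0139). RPS27L stood at 1.07 (adjusted p = 0.0149) and TRIAP1 at 0.77 (adjusted p = 0.0301). DDIT3, the stress factor CHOP, was lower at 42.6 ± 16.2 against 139 ± 34.5 CPM (-1.71, SE 0.27, adjusted p = 0.0140), though 28.0% of its exon positions lie in another gene. The pseudokinase gene TRIB3 was lower at 109 ± 33.6 against 342 ± 94.2 CPM (-1.65, adjusted p = 0.0162), and GTPBP2 at 35.6 ± 15.2 against 110 ± 18.4 CPM (-1.63, adjusted p = 0.0258). The G protein subunit gene GNAI1 was higher at 46.0 ± 28.2 against 7.03 ± 2.26 CPM (2.71, SE 0.59, adjusted p = 0.0395).

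Several of the largest changes lay in genes that share sequence or position with others, and these are uncertain. RPL26, a ribosomal protein gene (chromosome 17, 8377520 to 8383213), stood at 466 ± 64.5 against 36.4 ± 2.47 CPM in controls (log2 fold change 3.68, SE 0.14, edgeR adjusted p = 1.37e-07) and 479 ± 56.3 against 36.5 ± 1.83 CPM in knockdowns (3.72). Of its 50-base words 28.5% occur in another gene. The mitochondrial pseudogene MTND2P28 stood at 3.36 in both arms, UQCRHL, an intronless relative of UQCRH, at 2.86 and 2.62, and TOMM5, with 18.7% of its exon positions in another gene, at 2.35 and 2.44. MT-ATP8, which overlaps its neighbour over 22.2% of its positions, stood at 708 ± 75.0 against 138 ± 18.2 CPM (2.36, SE 0.21, adjusted p = 0.000246). The lowest were the antisense gene AC016909.1 (-2.95) and the pseudogenes RPL13AP25 (-2.38) and EEF1A1P6 (-1.94). Ribosomal protein genes took 5.87 ± 0.401% of counts in non-irradiated and 7.99 ± 0.849% in irradiated controls, and mitochondrial genes 5.49 ± 0.392% and 6.95 ± 0.350%.

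**Figure D4:**
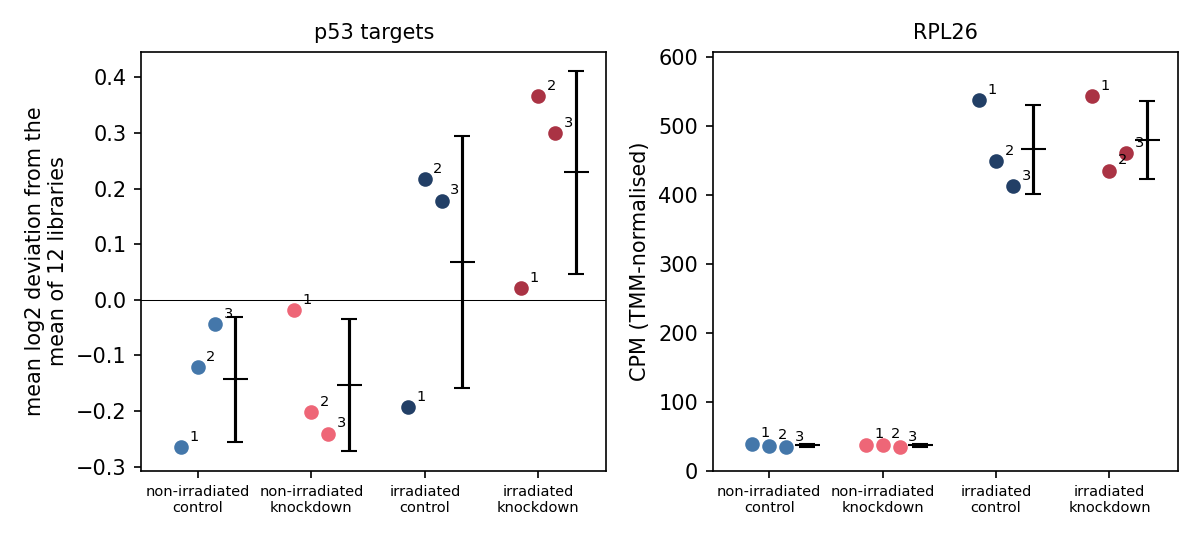
Left, mean log2 deviation of the p53 target list from the mean of the 12 libraries; right, RPL26 in TMM-normalised CPM on an axis from 0; points are libraries marked by replicate, bars the mean ± SD of 3. The p53 means run from -0.26 to -0.02 without irradiation, from 0.18 to 0.37 in irradiated replicates 2 and 3, and stand at -0.19 and 0.02 in irradiated replicate 1, while RPL26 separates the irradiation states in all 12.

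In controls 389 genes were called between the irradiation states, 238 higher and 151 lower. Of the 389, 268 were protein-coding and 91 pseudogenes. All 389 had separated libraries, as had 27.6% of tested genes, against 10% by chance. Scaling by library size only moved the split to 170 higher and 444 lower, since it shifted the median of all genes to -0.157. The count was 39 and 24 without non-irradiated control replicates 2 and 3, and 194 and 104 without irradiated control replicates 1 and 2. Of 19 named genes called, RPL26, SNRPN, MT-ATP8, UQCRHL, MTND2P28, EEF1A1P6 and AC016909.1 stayed called whichever library was left out. These were the 7 that stayed without non-irradiated control replicate 2 or 3; without each of the other 4 libraries 14 to 17 stayed. A separate fit of only the 8096 genes with little shared sequence or position called 46. Of the 389 calls 123 lie in these genes, and 46 of the 123 were called again, so the others were lost on refitting.

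By list, irradiated controls had 22 of 33 p53 targets positive (median 0.19, camera adjusted p = 0.000744; adjusted p = 0.466 with an estimated correlation), with 4 called higher over all genes and 8 higher and 1 lower adjusted over the list alone. All 25 ATF4 targets were negative (median -0.74, camera adjusted p = 1.43e-11; adjusted p = 0.466 with an estimated correlation); DDIT3, TRIB3 and ATF3 were called and 7 were adjusted over the list alone. The mean of this list stood at -1.04 in irradiated control replicate 1 against 0.29 and 0.34 in replicates 2 and 3, and its median ran from -0.92 to -0.37 when 1 library was left out. All 35 G2/M genes were positive (median 1.35, camera adjusted p = 2.65e-16; adjusted p = 0.466 with an estimated correlation), 17 of them higher adjusted over the list alone. Over all genes only the mitotic cyclin CCNB1 was called, at 101 ± 8.07 against 39.9 ± 18.7 CPM (1.35, SE 0.27, edgeR adjusted p = 0.0301). Of 39 replication genes 38 were positive (median 0.92, camera adjusted p = 7.47e-05; adjusted p = 0.554 with an estimated correlation) and none was called, over all genes or adjusted over the list alone. All 13 mitochondrial messenger RNAs were positive (median 0.43, camera adjusted p = 2.42e-09; adjusted p = 0.131 with an estimated correlation), MT-ATP8 being called, and 10 were adjusted over the list alone. Of 24 Sm genes 22 were positive (median 0.33, camera adjusted p = 5.67e-06; adjusted p = 0.466 with an estimated correlation). SNRPN was called (1.63, adjusted p = 0.000283; 39.2% of its exon positions lie in another gene) and 8 were adjusted over the list alone. The mean of the Sm list stood at 0.44 in irradiated control replicate 1 against -0.01 and -0.06 in replicates 2 and 3. The G2/M mean stood at 0.49 in non-irradiated control replicate 1 against -1.86 and -1.25 in replicates 2 and 3. Leaving out 1 library in turn moved the medians from 1.02 to 2.40 for G2/M, 0.19 to 0.46 for Sm genes, 0.13 to 0.33 for p53 targets and -0.04 to 1.21 for replication. Of these 4 only the replication call ended, without irradiated control replicate 1 (adjusted p = 0.918).

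Methylosome genes (11 of 12 positive, median 0.27, camera adjusted p = 0.0104), homologous recombination (24 of 28, 0.31, 0.0353) and cholesterol genes (20 of 22, 0.34, 0.00158) also ranked higher in irradiated controls. With an estimated correlation these stood at adjusted p = 0.466, 0.536 and 0.466. No member was called over all genes, and adjusted over the list alone 1 methylosome gene was. Without irradiated control replicate 1 the replication (-0.04, adjusted p = 0.918), recombination (0.08, 0.290) and methylosome (0.17, 0.0956) calls ended. The recombination call also ended without non-irradiated control replicate 2 (adjusted p = 0.130) or 3 (0.0883). Adjusted p over the alternatives ran from 4.53e-08 to 0.918 for replication, 0.000811 to 0.536 for recombination and 0.00487 to 0.466 for the methylosome. Lists not called were end joining (-0.01, adjusted p = 0.908), Fanconi anemia (0.24, 0.207), interferon (-0.15, 0.145), neuroendocrine (-0.21, 0.232), fibroblast (0.26, 0.232), basal epithelial (0.38, 0.908) and LCP1 (1.16, 0.237). Adjusted over the list alone LCP1 was higher and 1 neuroendocrine gene lower. Interferon passed without non-irradiated control replicate 3 (adjusted p = 0.0441) and fibroblast markers without non-irradiated control replicate 1 (0.00342). With 1 library left out in turn, the interferon median ran from -0.23 to -0.01 and the fibroblast median from -0.01 to 1.00. In these fits the highest camera adjusted p was 0.456 and 0.680.

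In knockdown cells 6 of 33 p53 targets were called higher and 5 of 25 ATF4 targets lower in the irradiated libraries, and the list calls given below were again all lost with an estimated correlation. The p53 target mean of irradiated knockdown replicate 1 was 0.02, below replicates 2 and 3. SESN1 stood at 227 ± 26.5 against 114 ± 14.2 CPM (log2 fold change 1.00, SE 0.14, edgeR adjusted p = 0.00499) and BTG2 at 199 ± 16.7 against 94.8 ± 23.5 CPM (1.07, SE 0.17, adjusted p = 0.00892). FAM129A, induced by stress in other settings, was lower at 1.77 ± 0.877 against 23.6 ± 9.97 CPM (-3.73, SE 0.80, adjusted p = 0.0332), and the neutral amino acid transporter SLC1A4 at 3.48 ± 1.29 against 18.5 ± 5.16 CPM (-2.40, SE 0.44, adjusted p = 0.0170). HMOX1, which degrades heme, was lower at 9.67 ± 4.23 against 36.3 ± 12.6 CPM (-1.90, adjusted p = 0.0260) and HEG1 by -1.69. MRPL12 stood at 3.29, but 68.2% of its exon positions lie in another gene. The serine synthesis gene PHGDH was lower at 245 ± 19.6 against 581 ± 115 CPM (-1.25, adjusted p = 0.0332).

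There were 615 calls in knockdown cells, 374 higher and 241 lower, of which 456 were protein-coding and 96 pseudogenes. All 615 had separated libraries, as had 29.8% of tested genes, against 10% by chance. Scaling by library size only gave 224 higher and 621 lower. The count was 217, 76 and 139 without non-irradiated knockdown replicates 1, 2 and 3, and 280, 93 and 220 without irradiated knockdown replicates 1, 2 and 3. Of 25 named genes called, RPL26, SESN1, SNRPN, TOMM5, MTND2P28, MT-ATP8, UQCRHL, MRPL12 and AC016909.1 stayed called whichever library was left out. With irradiated knockdown replicates 1, 2 and 3 left out in turn 18, 10 and 13 of the 25 stayed, and with non-irradiated knockdown replicates 1, 2 and 3 left out 11, 10 and 14. The separate fit of only genes with little shared sequence or position called 56. Of the 615 calls 230 lie in these genes, and 56 of the 230 were called again. The 2 irradiation comparisons, which share no library, had 167 higher and 80 lower genes in common, against 5.18 and 2.12 for independent lists, and none in opposite directions. They are not independent. Both hold any other difference between the tables, their libraries correlate as pairs within a table, and 1 fit gave the spread for both. In fits of only the 6 libraries compared the overlap was 38.

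By list, irradiated knockdowns had 29 of 33 p53 targets positive (median 0.36, camera adjusted p = 3.64e-08; adjusted p = 0.503 with an estimated correlation), 6 of them called higher over all genes and 10 adjusted over the list alone. ATF4 targets were negative in 24 of 25 (median -0.79, camera adjusted p = 2.87e-13; adjusted p = 0.503 with an estimated correlation), with 5 called, DDIT3 (-1.52), TRIB3 (-1.43) and SLC3A2 (-0.79) among them, and 15 adjusted over the list alone. Mitochondrial messenger RNAs were positive in 12 of 13 (median 0.33, camera adjusted p = 8.18e-06; adjusted p = 0.475 with an estimated correlation); MT-ATP8 (2.10) and MT-ND5 (0.56) were called, and 2 adjusted over the list alone. Of 24 Sm genes 23 were positive (median 0.24, camera adjusted p = 0.000458; adjusted p = 0.604 with an estimated correlation), SNRPN (1.41) alone being called either way. In contrast to the controls, 37 of 39 replication genes (median -0.67, camera adjusted p = 0.000215; adjusted p = 0.604 with an estimated correlation) and 31 of 35 G2/M genes (-0.56, 0.00579; adjusted p = 0.642 with an estimated correlation) were negative. No member of either was called, over all genes or adjusted over the list alone. The replication mean stood at 0.72 in irradiated knockdown replicate 1 against -0.67 and -0.59 in replicates 2 and 3. Leaving out 1 library in turn moved the medians from -1.05 to -0.40 for replication, -0.99 to -0.39 for G2/M, 0.29 to 0.55 for p53 targets and 0.13 to 0.33 for Sm genes, and of these 4 only the G2/M call ended, without knockdown replicates 2 or 3 of either table (highest adjusted p = 0.116).

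Homologous recombination (22 of 28 negative, median -0.26, camera adjusted p = 0.0430) and Fanconi anemia genes (14 of 18 negative, -0.22, 0.0392) also ranked lower in irradiated knockdowns. Cholesterol (20 of 22 positive, 0.21, 0.0221) and methylosome genes (0.22, 0.0340) ranked higher. With an estimated correlation each of these 4 stood at adjusted p = 0.604. In the methylosome list CLNS1A (0.49) and PRMT3 (0.48) were called higher; adjusted over the list alone the counts were equal, and no recombination, Fanconi or cholesterol gene was called over all genes or over the list alone without the block. The recombination, Fanconi and G2/M calls each ended without non-irradiated knockdown replicate 2 (adjusted p = 0.217, 0.158 and 0.116), replicate 3 (0.131, 0.0718 and 0.0786), irradiated knockdown replicate 2 (0.126, 0.149 and 0.0509) or replicate 3 (0.214, 0.136 and 0.0950). The methylosome call ended without irradiated (adjusted p = 0.114) or non-irradiated knockdown replicate 1 (0.117). The cholesterol call ended without non-irradiated knockdown replicate 2 (adjusted p = 0.0525) or 3 (0.228). The lowest and highest adjusted p over the alternatives were 0.000593 and 0.604 for recombination, 0.00198 and 0.604 for Fanconi, 7.00e-16 and 0.642 for G2/M, 0.0195 and 0.604 for the methylosome and 3.11e-06 and 0.604 for cholesterol. Lists not called were end joining (-0.07, adjusted p = 0.762), interferon (-0.15, 0.116), neuroendocrine (-0.25, 0.291), fibroblast (0.04, 0.522), basal epithelial (-0.03, 0.762) and LCP1 (0.70, 0.486), of which interferon passed without non-irradiated knockdown replicate 3 (0.0421). The interferon median ran from -0.15 to -0.02 with 1 library left out in turn (highest camera adjusted p = 0.474). Adjusted over the list alone 1 neuroendocrine gene was lower.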

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

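Of the tests in this part, the other splits of the samples, the length trends and the thinning to equal depth were planned; the tests of shared sequence, of p53 levels, of wrong labels, of exchanged libraries, of the pair changes and the splits of whole pairs were chosen after the result was seen.

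The 5 gene lists below stand here because the knockdown effect on them differed between the irradiation states in a test of that difference. The median log2 difference, irradiated minus non-irradiated, was -1.95 for G2/M and mitosis genes (camera adjusted p = 1.95e-68) and -1.25 for DNA replication and G1/S genes (adjusted p = 1.18e-34). It was -0.53 for homologous recombination (adjusted p = 7.41e-11), -0.53 for the Fanconi anemia pathway (adjusted p = 9.53e-08) and 0.14 for p53 targets (adjusted p = 0.00458). With an estimated correlation none passed, at adjusted p = 0.103, 0.184, 0.170, 0.170 and 0.777.

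The first pattern is that the cell cycle lists stood higher in the knockdown library of non-irradiated pairs 2 and 3, and lower in that of all 3 irradiated pairs and, for G2/M, of non-irradiated pair 1. An exchange of control and knockdown libraries in a pair is argued against by PRMT5, whose knockdown to control ratio was at most 0.166 over the 6 pairs. Library depth is argued against by thinning all libraries to the size of the smallest, 14801939 counts, after which 98.9% of the difference of the mean G2/M changes was left (-2.19 against -2.21). That irradiation changes the effect of the knockdown may be the cause but stays open, since the exact permutation test of the 3 against 3 pair changes gave p = 0.2 for G2/M and p = 0.1, the smallest possible, for the replication list, whose pairs were fully separated (each 0.6 adjusted over the 18 lists). The G2/M level also ranged by 2.35 on the log2 scale over the 3 non-irradiated controls, so differences between cultures in growth at harvest, which were not tested, stay open too.

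The second pattern is the excess of genes that share exon positions or sequence with another gene among the irradiation calls: 62.8% of 757 calls against 52.5% of other tested genes (Fisher's exact test, odds ratio 1.53, 95% interval 1.31 to 1.78, p = 2.63e-08). Reads of overlapping or near-identical genes assigned differently in the 2 tables may account for part of these calls, since knockdown calls made within a table showed no such excess (odds ratio 0.855, interval 0.666 to 1.10; with the block 0.879, 0.823 to 0.938). RPL26, MTND2P28, RPL13AP25 and EEF1A1P6 belong to this group. Shared reads are argued against as the whole cause by at least 46 calls (56 in knockdowns) in a fit of only genes with little shared sequence or position, and a gene length trend by the 97.4% of the median absolute fold change that the 282 calls of the main fit with little sharing kept once the trend was subtracted. Irradiation stays open for them: p53 targets stood above every non-irradiated library in 5 of the 6 irradiated ones, but irradiation and table cannot be told apart.

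The third pattern is the irradiated pair numbered 1, which stands at 79.7 and 68.6 on the first principal component (38.0% of variance), while the other 10 libraries lie between -44.6 and 13.2. A gene length trend in that pair is argued against, since 98.4% of the gap was left after subtracting it (54.5 against 55.3). The p53 target mean of the pair's control, -0.19, lay within the non-irradiated range (-0.26 to -0.02) and that of its knockdown, 0.02, was 0.379 SD above the highest non-irradiated library. Both were below irradiated pairs 2 and 3 (0.18 to 0.37). Single p53 targets go with the label: of the 7 and 12 called higher in controls and knockdowns in a fit without this pair, 5 and 9 stood above every non-irradiated library in its control and knockdown, BTG2 (136 and 184 against at most 121 CPM) and SESN1 (200.5 and 207.5 against at most 132 CPM) among them. Since any other difference between the tables would do the same, a pair labelled irradiated that had not been irradiated stays open. A wrongly labelled non-irradiated pair is argued against as the cause of the separation itself, because the pair lay 2.73 SD of the other 10 libraries beyond all of them, non-irradiated ones included. No biological explanation of the separation was tested.

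Other splits of the same libraries were counted for each comparison. For single genes the real split gave 265, 51, 389 and 615 calls in the order knockdown without and with irradiation, then irradiation in controls and in knockdowns, and the highest other split gave 3, 0, 0 and 0; the real split was the only 1 of 10 with as many calls. For gene lists the real splits gave 8, 6, 10 and 11 calls and the highest others 10, 7, 11 and 10, with 4, 3, 3 and 1 of 10 splits giving as many. With the block the real split called 4776 and 1974 genes and no other of the 4 splits called any, so 1 of 4 gave as many in each. All of these splits are too few for a share under 0.05. For the difference of the knockdown effects, 59 of 100 splits that exchange single libraries between irradiation states gave at least the 350 genes at an unadjusted p under 0.05, up to 3279, and 82 of 100 gave at least 5 lists, up to 11. These splits decide nothing, since an unequal exchange in the 2 arms puts the irradiation change into the difference: the median was 2832 genes in the 10 splits most unequal in this way and 293.5 in the 40 equal ones, 18 of which reached 350. They also part same-numbered libraries. Exchanging whole pairs, with the block, the real split gave 2093 genes at an unadjusted p under 0.05 and the highest other 1232, with 1 of 10 as many. For lists it gave 7 and the highest other 10, with 4 of 10 as many. These are again too few for a share under 0.05.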

How the results depend on the processing

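Fixed in advance were the alternatives of scaling, filter, tool, block, single left-out libraries, 6-library fits, fold and list test; all tests that leave out a pair, restrict genes by shared sequence, or combine DESeq2, fry or the overlap of calls with a block were chosen after the data were seen. Over all alternatives, values of named genes stayed on their side of the threshold in 6037 cases, passed it newly in 456, lost it in 294 and reversed while called in 0; of the 6037, 94 changed sign, uncalled before and after. List values did so in 1073 (101 with a changed sign of the test), 59 and 163, and 1 reversed: DNA replication and G1/S, knockdown with irradiation, at 0.44 without irradiated control replicate 1 (-0.11 and not called without the whole irradiated pair 1), in a range of -0.94 to 0.44 over single left-out libraries. Of counts and leading values 137 kept within their bounds, 69 moved beyond them, 3 rose from no calls and 9 fell to none. Why counts moved was not tested. Fewer samples alone do not set a count, since leaving out 1 library gave 4 to 254 genes for the knockdown with irradiation.

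PRMT5 kept its call under every alternative that tested it (the fit of genes with little shared sequence leaves it out), from -2.74 to -2.59 without and -2.97 to -2.75 with irradiation when 1 library was left out. Leaving out 1 library in turn gave 31 to 341 genes for the knockdown without irradiation, 4 to 254 with it, 24 to 341 for irradiation in controls, 76 to 280 in knockdowns and 0 for the difference. Lists called ran from 7 to 10, 5 to 9, 6 to 11, 7 to 10 and 4 to 8 in that order, the extremes including 6 without irradiated control replicate 1, 7 without non-irradiated knockdown replicate 2, and 8 without non-irradiated control replicate 1 or irradiated knockdown replicate 1.

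For the knockdown without irradiation (265 genes) the replicate block gave 4776, DESeq2 995, DESeq2 with the block 3599, the 6 libraries alone 1486, genes with little shared sequence 152 and a fold of at least 2 104. Without the irradiated pair 1 it was 2564, or 5175 with the block, and with the block without the non-irradiated pair 1 5234. The irradiated libraries are not compared here. They enter only through the gene filter, the scaling and the spread shared by the fit, so the 265 depends on that sharing. Which of these acted was not tested. For the knockdown with irradiation (51 genes) the same settings gave 1974, 246, 1465, 1, 18 and 27, and 326, 1847 and 3449. The difference (0 genes) gave 61 in DESeq2 with the block, and without the non-irradiated pair 1 47, or 712 with the block. Beyond these counts and the list and gene calls given with each comparison, the replicate block within tables changed no camera call of the methylosome, repair, cell cycle, p53, ATF4 or marker lists and ended none of the named genes' calls.

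For irradiation in controls (389 genes) library size only gave 614, no filter 592, the stricter filter 201, DESeq2 1305, the 6 libraries alone 64, little shared sequence 46, a fold of at least 2 211 and leaving out the irradiated pair 1 868. For irradiation in knockdowns (615 genes) DESeq2 gave 1363, the 6 libraries 344, little shared sequence 56, a fold of at least 2 243, and leaving out the irradiated or the non-irradiated pair 1 1806 and 275. In the main fit 123 calls in controls and 230 in knockdowns lie in genes with little shared sequence, so many were lost on refitting. Across tables the samples share only a number (same-number correlations in the same arm -0.150 to 0.143), and a block on it called 965 and 1157 genes.

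With an estimated correlation 0 lists were called in each of the 5 comparisons, where the preset correlation called 8, 6, 10, 11 and 5. Fry called 0, 0, 1, 1 and 0, or 4, 2, 2, 2 and 0 with the block, which ran across tables for irradiation. Without the irradiated pair 1 irradiation in controls kept 6 lists. The overlap of knockdown calls was 49, 1 in the 6-library fits and 1478 with the block; that of irradiation calls was 247, 38 in the 6-library fits and 576 with the block across tables. Depth limits genes below about 0.203 CPM, the level of 3 counts in the smallest library.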

Other observations

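The seed, mitochondrial and neighbourhood tests below were chosen after the result was seen, except the search for over-represented words, which was planned as a test before its outcome was known.

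The genes lowered by knockdown in both irradiation states hold several of the secretory pathway and of membranes, named here after their values were seen. EIF2AK3, the kinase PERK that senses unfolded protein in the endoplasmic reticulum, stood at -1.01 without and -0.86 with irradiation (edgeR adjusted p = 0.0101 and 0.0412), though part of its exons overlap another gene. The coatomer subunit ARCN1 stood at -0.76 and -0.58, the lysosomal thioesterase PPT1 at -0.81 and -0.74, the ER-shaping protein ARL6IP1 at -0.81 and -1.35, and the beta-secretase BACE1 at -0.57 and -0.61. FAM3C, which encodes a secreted factor, stood at -1.47 and -1.19. BACE1, FAM3C and ARL6IP1 share sequence with other genes and are uncertain. The actin regulator PFN2 stood at -0.98 and -0.85, the histone demethylase PHF2 at -1.02 and -1.11, and the bHLH factor HES6 at -0.73 and -0.79. No enrichment was tested for these groups.

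That 48 of the 49 shared calls were lower led to a search of 3′ untranslated regions for words that a small RNA would pair with. With the block 677 shared genes were higher and 801 lower, so this imbalance depends on the fit. Among 11564 words of 7 bases, TTCCCTA was the most over-represented in 44 of the 47 shared lower genes other than PRMT5 that have such a region: 20 genes held it against 6.32 expected (z 6.39). The permutation p over 1000 length-matched gene sets was 0.00200. Carriers include RNF14, GDPD1, MCCC2, ABHD2, UBAP1, NIPAL3, SLC35D2, LRRC8B, BACE1 and FAM3C. The same word led among the 1931 words that occur in PRMT5 messenger RNA, with the same permutation p. There it occurs once, in coding sequence of exon 16 of 17 on the minus strand of chromosome 14 at 22922181 to 22922187 (GRCh38), at transcript position 1974 of 2531.

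A candidate explanation is that the hairpin's guide strand pairs with PRMT5 around this word and that its seed also lowers other messenger RNAs with the word. In a test on genes outside the shared lower genes, the 1530 with the word in their 3′ untranslated region stood lower than the 11005 without it in 6 of 6 pairs, by -0.07 on average (SD 0.00725, range -0.08 to -0.06). The exact sign permutation p was 0.0313, the smallest that 6 pairs can give. Among 16243 words it ranked 1 with irradiation (z -7.21) but 132 without, where ATATTAT led (z -7.66). Both predictions were met, but the rank of 132 without irradiation does not set this word apart there. The sign test cannot tell a seed from any other trait of these genes that repeats in every pair. It used the libraries in which the word was found, and genes called lower in only 1 state stayed in it. It is therefore not an independent check. Whether some genes lowered in both states, RNF14 among them, are lowered by the hairpin and not by loss of PRMT5 stays open. The hairpin's sequence is not given in the sources used here, and a second hairpin was not analysed here.

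PSMB5 lies 87.0 kb from PRMT5 and was lower in both states. Loss of expression across the whole neighbourhood is an unlikely cause: the 27 tested genes within 500 kb had a median log2 fold change of -0.053 with irradiation and -0.02 without, against -1.39 and -1.27 for PSMB5 (SD of the 27 genes 0.37 and 0.38). With the block 4 of the 27, PSMB5 included, were called lower in both, 14.8% against 4.64% of other genes (Fisher's exact test, p = 0.0350). That p counts PSMB5, which prompted the test, and was not computed without it. A smaller effect on part of the neighbourhood therefore stays open.

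Mitochondrially encoded messenger RNAs were higher with doxycycline, an inhibitor of bacterial and mitochondrial translation, in 6 of 6 pairs, by 0.17 to 0.49. The ATF4 list was lower in the knockdown library of 5 of the 6 pairs (range -1.07 to 0.27). This argues against mitochondrial stress with a net rise of ATF4 targets. A rise by doxycycline that the knockdown outweighed stays open, since both always came together. Doxycycline and knockdown cannot be told apart here as the source of the mitochondrial rise.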
